A study of Mus musculus with 8 samples.

How the data were processed

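Livers of 8 mice after bile duct ligation were profiled by RNA-seq, 4 wild-type controls and 4 mice labelled as overexpressing Myc in endothelial cells. Total RNA was extracted and libraries were made with an mRNA kit, per the labels' protocols; sex, litter, batch and read strand are not given in the sources used here. Reads were aligned with HISAT2 and quantified with StringTie on mm10, per the submitters' processing notes, which give no versions.

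Each deposited file lists 53816 gene IDs with their coordinates. TPM, the main unit, was deposited by the authors and sums to 1000000 in each library. FPKM was deposited by the authors beside it, per the file headers. Coverage, a signal not scaled for depth, is also given per the file headers. No read counts were used. The modal ratio of coverage to FPKM gives aligned bases, 5.29 to 6.74 Gb per library, on the assumption that StringTie divides by total aligned bases. Between 10 and 15 repeated rows per library were summed. No file holds rows for chromosome Y. Of the IDs, 98.3% matched GENCODE M21 with their version, and 100% of these had identical coordinates. Gene types were taken from GENCODE M21 by ID without the version, which matched 99.6%.

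Differences were tested on log2(TPM + 1) with limma 3.58.1 (R 4.3.3), trended and robust, two-sided, for 13055 genes with a mean of at least 1 TPM, with Benjamini-Hochberg adjustment at 0.05. The 42 gene lists (877 genes), the limma and camera tests and the rule for named genes were fixed before the data were examined. Of the library measures, that plan named genes detected and the shares of top, mitochondrially encoded and haemoglobin genes. It did not name the exact permutation of list means. The lists covered Myc targets, endothelial and other liver cell types, blood, matrix, bile acid, metabolic, stress and sex-biased genes. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera compares the members with the other tested genes, so its direction need not be that of the members' own mean or median. Library measures and Myc were compared by exact permutation over 70 assignments, whose smallest two-sided p is 0.0286, and measures adjusted over 9. The other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

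Myc was named first by that rule. It then took up to 12 genes per direction past the threshold with separated values, at least 2 TPM in the higher group and an established symbol. Where fewer pass, it took 10 per direction by smallest unadjusted p, named as not passing. Since 0 genes passed, those 10 were taken, keeping the symbol and level conditions. The rule also took up to 4 members with the smallest p from each described list. That 2 per list were named, which of the lists that did not pass were described, and that the symbol and level conditions were kept were settled after the data were seen. The values of 1 such list member are not reported here. Values of 0 occurred 19 times in genes whose mean over the other 7 libraries was at least 10 TPM, 17 of them in the Mup, Sult2a, Cyp or Ugt families, where reads can be shared between near-identical genes.

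The pipeline was tested on simulated data of the same 13055 genes with 200 changed genes in each of 5 runs: 58.4% of 2-fold and 91.8% of 4-fold changes were recovered, with 42 false calls over the runs. The changed genes were drawn only from those with a mean log2(TPM + 1) of at least 3, and values were drawn independently for each gene. Of the 200 changed genes per run 100 had each size, so the shares recovered need not hold where few genes change. Both lists whose members were all shifted by 1 log2 unit were recovered, and 1 other list was called. Since the simulated genes were independent, this does not check the list test on correlated genes. Alternatives covered the pseudocount (0.1 and 5), the filter, scaling, FPKM in place of TPM, the variance model, array weights, a replicate block and leaving out each library. A covariate of log2 Xist and a run on protein-coding genes only were chosen after seeing the data.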

Results

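RNA was sequenced from the livers of 8 mice after bile duct ligation, a surgical block of bile flow that leads to cholestatic injury and fibrosis. Of these, 4 were wild-type controls and 4 carried, per the labels, an overexpression of Myc in endothelial cells. The comparison asks how endothelial Myc alters the transcriptome of the cholestatic liver, in whole tissue of which endothelial cells are a part. Aligned bases, derived from coverage and FPKM, ranged from 5.29 to 6.74 Gb per library. Means are given ± SD over 4 libraries per group. Log2 differences (Myc-labelled minus control) are given ± SE on the log2(TPM + 1) scale, which understates changes of low genes.

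Myc (ENSMUSG00000022346.15, chromosome 15, 61985391 to 61990374, mm10), the gene named in the labels, did not follow them. It stood at 272, 207, 554 and 89.2 TPM in control replicates 1 to 4. In the Myc-labelled replicates 1 to 4 it stood at 339, 356, 25.6 and 249 TPM, so the lowest of the 8 values lay in a library labelled Myc. The mean was 281 ± 198 TPM in the controls and 242 ± 152 TPM in the Myc-labelled libraries. The log2 difference was -0.45 ± 0.95, with a 95% interval of -2.68 to 1.77 (limma adjusted p = 1.0; exact permutation p = 0.714, two-sided). Without Myc-labelled replicate 3 the log2 difference was 0.43, and with array weights 0.23, neither past the threshold. The Myc log2 fold change was -0.03 without control replicate 3, -0.91 without control replicate 4, -0.79 without Myc-labelled replicate 1 and -0.82 without Myc-labelled replicate 2. Whether a transgene would be counted under this gene is not given in the sources used here. The libraries are called Myc-labelled throughout, and every direction below rests on those labels.

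**Figure D1:**
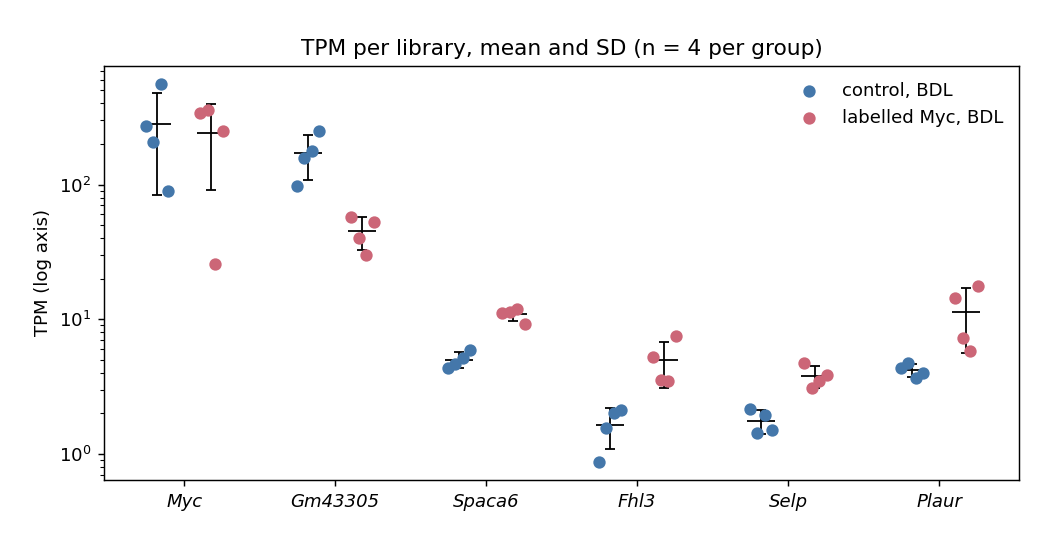
TPM (log axis) of 6 genes in each library; points are libraries, bars the mean and SD of 4 libraries per group. Myc overlaps between the groups, from 89.2 to 554 TPM in the controls and from 25.6 to 356 TPM in the Myc-labelled libraries, while Gm43305, Spaca6, Fhl3, Selp and Plaur do not overlap and did not pass the test over all genes.

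No gene passed an adjusted p of 0.05 over the 13055 genes tested. With limma 0 genes were higher and 0 lower, and at an unadjusted p under 0.05 there were 165 higher and 78 lower genes, where chance alone gives about 652.75 together. That split was 151 higher and 180 lower after median-of-ratios scaling, and 166 higher and 152 lower after quantile normalization. Leaving out 1 library moved the higher genes to 574 without Myc-labelled replicate 3, 88 without Myc-labelled replicate 1 and 98 without Myc-labelled replicate 4. The lower genes moved to 184 without Myc-labelled replicate 1, 47 without control replicate 4, 119 without control replicate 1 and 118 without control replicate 2. With array weights limma called 0 higher genes and 1 lower, Gm43305 (adjusted p = 0.0469). Those weights were 3.32 for Myc-labelled replicate 2, 0.42 to 0.82 for the other Myc-labelled libraries and 0.588 to 1.62 for the controls. Within the Myc-labelled group, results with array weights thus lean most on replicate 2. The median 95% interval reached 0.47 log2 units to either side. In simulated data of the same 13055 genes 58.4% of genes changed 2-fold and 91.8% of genes changed 4-fold were recovered. Each run held 200 changed genes, 100 of each size. An adjusted p is easier to pass when many genes change, so these shares need not hold where few do. The changed genes were drawn only from those with a mean log2(TPM + 1) of at least 3. Each gene was drawn independently, so these shares do not cover lower genes or variation that real libraries share across genes. All 4 values of one group lay above those of the other in 164 genes, 122 of them higher and 42 lower in the Myc-labelled libraries, against 373 (2.86% of genes) by chance.

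The smallest p belonged to the noncoding transcript Gm43305 (chromosome 14, 54292443 to 54297456), chosen after its values were seen, at 171 ± 63.7 TPM in the controls and 45.1 ± 12.5 TPM in the Myc-labelled libraries (log2 difference -1.87 ± 0.30, limma adjusted p = 0.509). Spaca6, a gene of sperm and egg fusion on chromosome 17, had the same adjusted p and stood at 5.03 ± 0.711 TPM in the controls and 10.9 ± 1.17 TPM in the Myc-labelled libraries. Among the other genes with the smallest p-values on the higher side, none of which passed, the LIM domain gene Fhl3 stood at 1.64 ± 0.563 against 4.95 ± 1.88 TPM and Pdlim7 at 5.55 ± 1.53 against 11.7 ± 4.62 TPM. Plaur, the urokinase receptor, measured 4.21 ± 0.456 against 11.3 ± 5.7 TPM, and the P-selectin gene Selp 1.76 ± 0.351 against 3.78 ± 0.695 TPM. The mitochondrial tRNA genes mt-Ty (106 ± 30.7 against 182 ± 25.2 TPM) and mt-Tr (6.69 ± 2.78 against 12 ± 2.29 TPM) were also on this side. The short RNA genes Mir5119 (0.567 ± 0.666 against 2.07 ± 0.476 TPM), within Cdk12, and Snord83b (1.37 ± 1.47 against 4.22 ± 0.911 TPM), within Rpl3, share their strand with those hosts, and the T cell receptor segment Trdj1 was listed at 0.0809 ± 0.162 against 5.84 ± 7.02 TPM.

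On the lower side, also without passing, Timp4, an inhibitor of metalloproteinases that overlaps Syn2 on the opposite strand, stood at 9.9 ± 9.1 against 1.15 ± 0.722 TPM and Acnat2, an acyltransferase, at 99.6 ± 29.1 against 48.7 ± 13.6 TPM. The phenol sulfotransferase Sult1a1, which overlaps Sgf29 on the opposite strand, measured 1154 ± 89.6 against 776 ± 123 TPM and the serine protease Prss36 4.32 ± 1.69 against 1.62 ± 0.72 TPM. Arhgef16 stood at 5.64 ± 0.896 against 3.39 ± 0.232 TPM, Tango2 at 83.6 ± 7.34 against 55.5 ± 13.6 TPM and the amino acid transporter Slc43a1 at 11.4 ± 1.24 against 7.27 ± 2.04 TPM. Fam107a measured 7.73 ± 4.2 against 2.61 ± 1.22 TPM, the sinusoidal endothelial gene Ehd3 22.7 ± 2.94 against 12.4 ± 5.66 TPM and the immunoglobulin segment Iglj1 3.23 ± 0.523 against 0.753 ± 1.23 TPM.

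Endothelial gene lists had 0 members past the threshold over all genes. Of the sinusoidal endothelial markers 16 of 19 were lower, with a median log2 difference of -0.21 (camera adjusted p = 1.30e-05, adjusted p = 0.857 with an estimated correlation). That median was -0.35 without Myc-labelled replicate 1 and -0.11 without Myc-labelled replicate 4. It was -0.11 with a pseudocount of 5. The centred log2 mean of these markers was 0.347 in Myc-labelled replicate 1, the highest of the 8 libraries. In replicate 2 it was -0.0557, within the control range of -0.0952 to 0.338. Only Myc-labelled replicates 3 and 4, at -0.281 and -0.506, lay below that range. The scavenger receptor Stab2 stood at 14 ± 2.41 against 10.1 ± 2.2 TPM. Of the pan-endothelial markers 13 of 21 were lower (camera adjusted p = 0.0388, adjusted p = 0.962 with an estimated correlation). Robo4 stood at 5.87 ± 0.955 against 4.11 ± 0.898 TPM and Ptprb at 7.59 ± 0.788 against 5.32 ± 1.84 TPM. The pan-endothelial call ended without control replicate 1 (camera adjusted p = 0.489), control replicate 4 (camera adjusted p = 0.263), Myc-labelled replicate 2 (camera adjusted p = 0.0599) and Myc-labelled replicate 4 (camera adjusted p = 0.471). Pan-endothelial genes also lost it with no filter (camera adjusted p = 0.0995), a mean of at least 5 TPM (camera adjusted p = 0.062), array weights (camera adjusted p = 0.145) and the Xist covariate (camera adjusted p = 0.251). Markers of capillarisation and endothelial activation did not pass as a list (camera adjusted p = 0.449). Adjusted over the list alone 1 of its 15 members, Selp, was higher (limma adjusted p = 0.0264). This adjustment does not correct for the testing of 42 lists. Selp overlaps Gm16548 on the opposite strand. Over its list alone, Selp stayed past the threshold in 12 of 19 other settings, over a range of 0.0146 to 0.102. The Selp call ended without control replicate 2 (limma adjusted p = 0.099), control replicate 3 (limma adjusted p = 0.0575), control replicate 4 (limma adjusted p = 0.102), Myc-labelled replicate 1 (limma adjusted p = 0.0684) and Myc-labelled replicate 4 (limma adjusted p = 0.085), and with the Xist covariate (limma adjusted p = 0.0536). Esm1 of the same list stood at 1.21 ± 0.531 against 2.54 ± 2.08 TPM. Angiocrine factors did not pass as a list (camera adjusted p = 0.888), with Hgf at 3.09 ± 1.3 against 4.64 ± 2.67 TPM and Pdgfa at 9.24 ± 3.21 against 11.5 ± 2.08 TPM. Adjusted over the list alone, 0 members of the other 41 lists passed.

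Lists of Myc targets had 0 members past the threshold, over all genes or adjusted over the list alone. Of the ribosome biogenesis targets 31 of 36 were higher, with a median log2 difference of 0.11 (camera adjusted p = 0.00884, adjusted p = 0.962 with an estimated correlation). That median was 0.04 without control replicate 1, 0.18 without control replicate 2, 0.06 without Myc-labelled replicate 1 and 0.18 without Myc-labelled replicate 3. It was 0.07 with median-of-ratios scaling. Over all tested genes the median log2 difference was 0.037. That background was -0.037 without Myc-labelled replicate 1, 0.115 without Myc-labelled replicate 3 and -0.00449 with median-of-ratios scaling. Counts of higher or lower members, in every list, do not correct for it. Nop58 stood at 4.96 ± 1.01 against 7.11 ± 1.44 TPM and Rrs1 at 21.2 ± 3.3 against 27 ± 4.74 TPM. The ribosome biogenesis call ended without control replicate 1 (camera adjusted p = 0.155), control replicate 4 (camera adjusted p = 0.26) and Myc-labelled replicate 4 (camera adjusted p = 0.0707). Ribosome biogenesis genes also lost it with array weights (camera adjusted p = 0.0946). Metabolic and other Myc targets did not pass (camera adjusted p = 0.804). Of these, Slc7a5 stood at 1.69 ± 0.546 against 2.83 ± 1.02 TPM and Mthfd2 at 1.64 ± 0.795 against 3.96 ± 3.27 TPM. Cytosolic ribosomal protein genes (camera adjusted p = 0.478) and cell cycle genes (camera adjusted p = 0.478) did not pass either. The cell cycle gene Birc5 stood at 2.94 ± 2.23 against 1.2 ± 0.65 TPM and Ccne1 at 2.17 ± 0.872 against 2.91 ± 0.847 TPM.

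Among matrix and injury lists, extracellular matrix genes were higher in 22 of 26 members (camera adjusted p = 0.0082, adjusted p = 0.962 with an estimated correlation). Their centred log2 mean was 1.21 in Myc-labelled replicate 1. In the other Myc-labelled libraries it was -0.589 to 0.102, within the control range of -0.74 to 0.229. Thbs1 stood at 2.78 ± 1.62 against 8.78 ± 4.7 TPM and the collagen gene Col15a1 at 1.01 ± 0.14 against 2.52 ± 1.51 TPM. The matrix call ended without control replicate 2 (camera adjusted p = 0.609) and Myc-labelled replicate 1 (camera adjusted p = 0.963). Matrix genes also lost it with a mean of at least 5 TPM (camera adjusted p = 0.111), FPKM in place of TPM (camera adjusted p = 0.0614) and array weights (camera adjusted p = 0.0648). TGF-beta response genes were higher in 14 of 17 members (camera adjusted p = 0.0114, adjusted p = 0.929 with an estimated correlation). Their centred log2 mean was 0.608 in Myc-labelled replicate 1, against -0.217 to 0.150 in the other Myc-labelled libraries. In control replicate 1 it was -0.578, against -0.160 to 0.127 in the other controls. The receptor gene Tgfbr1 stood at 9.6 ± 1.29 against 13.4 ± 2.43 TPM and Skil at 5.96 ± 1.79 against 8.64 ± 1.94 TPM. The TGF-beta call ended without control replicate 1 (camera adjusted p = 0.168) and Myc-labelled replicate 1 (camera adjusted p = 0.157). TGF-beta genes also lost it with array weights (camera adjusted p = 0.185).

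Endoplasmic reticulum stress genes were higher in 16 of 19 members (camera adjusted p = 0.0471, adjusted p = 0.962 with an estimated correlation). Asns stood at 6.37 ± 2.66 against 15.6 ± 9.22 TPM and Ddit3 at 6.12 ± 1.75 against 13.2 ± 7.95 TPM. The stress call ended without control replicate 3 (camera adjusted p = 0.158), control replicate 4 (camera adjusted p = 0.221) and Myc-labelled replicate 4 (camera adjusted p = 0.451). Stress genes also lost it with no filter (camera adjusted p = 0.117), FPKM in place of TPM (camera adjusted p = 0.0661), no trend or robust step (camera adjusted p = 0.056), array weights (camera adjusted p = 0.61) and the Xist covariate (camera adjusted p = 0.234). Stellate and myofibroblast markers did not pass (camera adjusted p = 0.345), with Acta2 at 3.24 ± 2.22 against 10.3 ± 7.6 TPM and Pdgfrb at 4.03 ± 0.851 against 5.99 ± 3.44 TPM. Cholangiocyte markers did not pass (camera adjusted p = 0.345), with Prom1 at 1.53 ± 0.768 against 2.8 ± 1.7 TPM and Spp1 at 172 ± 91.9 against 422 ± 366 TPM.

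Among blood and immune lists, neutrophil markers were higher in 11 of 11 members, with a median log2 difference of 0.64 (camera adjusted p = 8.11e-07, adjusted p = 0.857 with an estimated correlation). That median was 0.35 without Myc-labelled replicate 4. It was 1.21 with a pseudocount of 0.1 and 0.27 with a pseudocount of 5. Il1r2 stood at 1.63 ± 1.19 against 4.79 ± 2.12 TPM and Mmp9 at 1.19 ± 0.177 against 3.51 ± 2.4 TPM. Erythroid and platelet markers were higher in 7 of 7 members (camera adjusted p = 0.0082, adjusted p = 0.857 with an estimated correlation). Their centred log2 mean was nevertheless highest in control replicate 1, at 0.625, and lowest in control replicate 4, at -1.01. Control replicates 2 and 3 had -0.436 and -0.192, and the Myc-labelled libraries -0.0551 to 0.615. Alas2 stood at 7.65 ± 2.22 against 11.2 ± 3.52 TPM and the haemoglobin gene Hba-a1 at 228 ± 171 against 322 ± 90.7 TPM. The erythroid call ended without control replicate 2 (camera adjusted p = 0.051), control replicate 4 (camera adjusted p = 0.221) and Myc-labelled replicate 4 (camera adjusted p = 0.0599). Erythroid genes also lost it with the Xist covariate (camera adjusted p = 0.05004). Kupffer cell markers were lower in 12 of 12 members (camera adjusted p = 7.44e-06, adjusted p = 0.857 with an estimated correlation). The complement gene C1qc stood at 166 ± 21.4 against 124 ± 31 TPM and Timd4 at 15.1 ± 7.89 against 8.04 ± 3.12 TPM. Cytokines and chemokines did not pass (camera adjusted p = 0.194), with Ccl2 at 12.4 ± 6.6 against 42.1 ± 36.5 TPM and Ccl7 at 1.22 ± 1.66 against 2.25 ± 1.11 TPM. Interferon response genes did not pass (camera adjusted p = 0.078), with Rsad2 at 3.04 ± 3.23 against 3.78 ± 2.03 TPM and Ifit2 at 3.22 ± 3.45 against 1.83 ± 0.985 TPM.

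Hepatocyte markers were lower in 20 of 25 members (camera adjusted p = 0.00111, adjusted p = 0.857 with an estimated correlation). The urea cycle gene Cps1 stood at 1862 ± 298 against 1296 ± 451 TPM and Tdo2 at 939 ± 234 against 685 ± 251 TPM. The hepatocyte call ended without Myc-labelled replicate 1 (camera adjusted p = 0.274). Hepatocyte genes also lost it with array weights (camera adjusted p = 0.302). Periportal genes were lower in 12 of 16 members (camera adjusted p = 0.0122, adjusted p = 0.857 with an estimated correlation). Hal stood at 186 ± 17.8 against 136 ± 25.1 TPM and Hsd17b13 at 938 ± 123 against 720.2 ± 199 TPM. The periportal call ended without control replicate 3 (camera adjusted p = 0.11), control replicate 4 (camera adjusted p = 0.0687) and Myc-labelled replicate 1 (camera adjusted p = 0.191). Periportal genes also lost it with quantile normalization (camera adjusted p = 0.143) and array weights (camera adjusted p = 0.128). Xenobiotic genes were lower in 15 of 23 members (camera adjusted p = 0.0392, adjusted p = 0.929 with an estimated correlation), although Gsta1 stood at 65.5 ± 58.3 against 232 ± 150.0 TPM. The xenobiotic call ended without control replicate 1 (camera adjusted p = 0.152), control replicate 2 (camera adjusted p = 0.0712), control replicate 3 (camera adjusted p = 0.182), control replicate 4 (camera adjusted p = 0.128), Myc-labelled replicate 1 (camera adjusted p = 0.169) and Myc-labelled replicate 3 (camera adjusted p = 0.894). Xenobiotic genes also lost it with no filter (camera adjusted p = 0.153), a mean of at least 5 TPM (camera adjusted p = 0.0527), median-of-ratios scaling (camera adjusted p = 0.176), quantile normalization (camera adjusted p = 0.318), array weights (camera adjusted p = 0.61) and the Xist covariate (camera adjusted p = 0.05004).

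Cholesterol synthesis genes were lower in 20 of 21 members, with a median log2 difference of -0.22 (camera adjusted p = 9.20e-06, adjusted p = 0.929 with an estimated correlation). That median was -0.38 without control replicate 1, -0.11 without control replicate 2, -0.11 without control replicate 4, -0.37 without Myc-labelled replicate 1 and -0.06 without Myc-labelled replicate 3. It was -0.14 with the Xist covariate. Mvk stood at 69.6 ± 9.88 against 48.8 ± 9.77 TPM. Bile acid synthesis genes did not pass (camera adjusted p = 0.056), with Akr1d1 at 184 ± 23.5 against 138 ± 45.8 TPM and Cyp27a1 at 479 ± 90.6 against 383 ± 126 TPM. Female-biased liver genes were lower in 10 of 11 members (camera adjusted p = 0.00145, adjusted p = 0.906 with an estimated correlation). Sult3a1 stood at 1.69 ± 1.13 against 0.543 ± 0.769 TPM and Sult1e1 at 243 ± 108 against 128 ± 89.7 TPM. The female-biased call ended without control replicate 1 (camera adjusted p = 0.0718) and Myc-labelled replicate 4 (camera adjusted p = 0.168). Female-biased genes also lost it with no filter (camera adjusted p = 0.0661), array weights (camera adjusted p = 0.927) and the Xist covariate (camera adjusted p = 0.0641). Xist, transcribed from the inactive X chromosome, stood at 32.8, 41.0 and 35.2 TPM in control replicates 1, 2 and 4 and at 43.3 and 33.6 TPM in Myc-labelled replicates 1 and 2. It was at 0.0454 to 0.0574 TPM in control replicate 3 and Myc-labelled replicates 3 and 4. In that order, these libraries had centred log2 means of -0.855, -1.93 and -1.82 for female-biased genes, against 0.403 to 1.41 elsewhere. For male-biased genes they had 0.705, 1.07 and 0.881, against -0.849 to 0.0342 elsewhere. By these genes the groups held unequal numbers of livers with a male pattern, though the labels give no sex.

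Mitochondrially encoded genes were higher in 13 of 13 members (camera adjusted p = 2.95e-06, adjusted p = 0.857 with an estimated correlation). The gene mt-Nd2 stood at 5115 ± 321 against 7533 ± 1244 TPM and mt-Nd5 at 3615 ± 638 against 4648 ± 443 TPM. Their share of TPM in percent was 8.05 ± 0.815 in the controls and 9.92 ± 0.57 in the Myc-labelled libraries (exact permutation p = 0.0286, adjusted p = 0.257). It was higher in 4 of 4 Myc-labelled libraries than in every control, and this p is the smallest that 70 assignments allow.

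**Figure D2:**
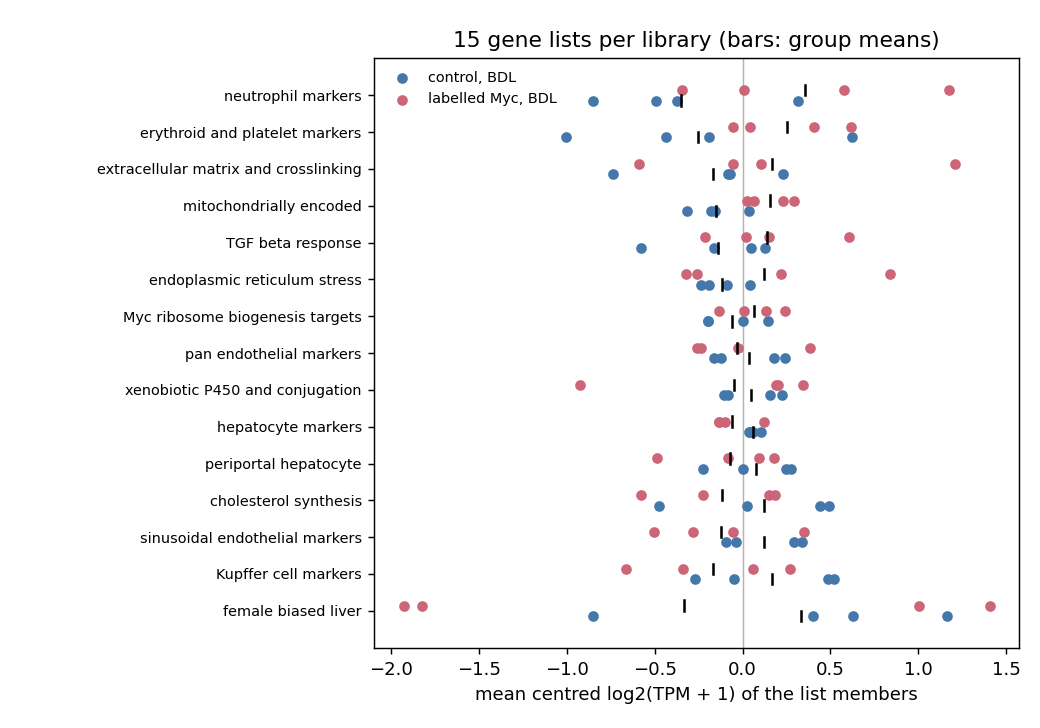
Mean of centred log2(TPM + 1) over the members of each of the 15 lists that passed camera with a preset correlation; points are libraries and black bars group means. The ranges of the 2 groups overlap in all 15 lists, and 0 of the 15 passed with an estimated correlation.

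Together 7 lists were higher and 8 lower with a preset correlation of 0.01. With an estimated correlation camera called 0 of 42 lists, with 1 at an unadjusted p under 0.05, and fry called 0, with a smallest adjusted p of 0.764. The estimated correlation had a median of 0.476 over the 15 lists. By exact permutation of the library means 0 of 42 lists had an unadjusted p under 0.05. Leaving out Myc-labelled replicate 3 gave 16 higher lists and leaving out Myc-labelled replicate 4 gave 4. With array weights 6 of the 15 stayed called. When each library was left out in turn, 5 lists stayed called throughout, namely sinusoidal endothelial, neutrophil, Kupffer cell, mitochondrially encoded and cholesterol synthesis genes.

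The remaining lists did not pass with the preset correlation. Their adjusted p-values from camera were 0.466 for bile acid and lipid transporters, 0.73 for pericentral and Wnt genes, 0.94 for acute phase genes and 0.235 for immediate early genes. Further values were 0.94 for monocyte and macrophage markers, 0.478 for T and NK cell markers (2 members measured), 0.478 for B and plasma cell markers (3 measured), 0.308 for mesothelial markers and 0.478 for pancreas and gut markers (1 measured). For p53 and senescence the adjusted p was 0.898, for the Notch pathway 0.898, for glycolysis 0.21, for oxidative phosphorylation 0.345, for fatty acid oxidation 0.911 and for lipogenesis 0.911. For male-biased genes it was 0.804 and for Xist, the 1 measured member of the Y-linked list, 0.409. The test differed in direction from the median in 7 of the 42 lists and from the mean in 7. Both differed for cytosolic ribosomal protein, angiocrine, acute phase, Notch, fatty acid oxidation and male-biased genes. For pericentral genes it was the median alone, and for lipogenesis the mean alone.

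Some lists that did not pass were called under 1 setting or more, or when 1 library was left out. With quantile normalization glycolysis genes (camera adjusted p = 0.0481) were called higher. With FPKM in place of TPM bile acid synthesis genes (camera adjusted p = 0.0416) and interferon response genes (camera adjusted p = 0.019) were called lower. With array weights cytosolic ribosomal protein genes (camera adjusted p = 9.93e-04), cholangiocyte markers (camera adjusted p = 0.0104), pericentral genes (camera adjusted p = 0.00676) and oxidative phosphorylation genes (camera adjusted p = 0.00358) were called higher, and interferon response genes (camera adjusted p = 0.00241) and male-biased genes (camera adjusted p = 0.00975) were called lower. With the Xist covariate male-biased genes (camera adjusted p = 0.00288) were called lower. With a pseudocount of 5 interferon response genes (camera adjusted p = 0.0195) were called lower. With protein-coding genes only bile acid synthesis genes (camera adjusted p = 0.0466) were called lower. Cytosolic ribosomal protein genes (camera adjusted p = 5.96e-05) were called higher without control replicate 1. Interferon response genes (camera adjusted p = 0.0158), cell cycle genes (camera adjusted p = 0.0299) and lipogenesis genes (camera adjusted p = 0.023) were called lower without control replicate 1. Cytokines and chemokines (camera adjusted p = 0.0207) were called higher without control replicate 2. Bile acid synthesis genes (camera adjusted p = 0.0125), interferon response genes (camera adjusted p = 0.00101) and cell cycle genes (camera adjusted p = 0.0109) were called lower without control replicate 2. Acute phase genes (camera adjusted p = 0.0447) and interferon response genes (camera adjusted p = 0.00206) were called lower without control replicate 3. Stellate markers (camera adjusted p = 0.0358), cytokines and chemokines (camera adjusted p = 0.00541) and interferon response genes (camera adjusted p = 5.55e-06) were called higher without control replicate 4. Cytosolic ribosomal protein genes (camera adjusted p = 1.07e-08) and oxidative phosphorylation genes (camera adjusted p = 0.0342) were called lower without control replicate 4. Mesothelial markers (camera adjusted p = 1.38e-04) and fatty acid oxidation genes (camera adjusted p = 0.0289) were called lower without Myc-labelled replicate 1. Bile acid synthesis genes (camera adjusted p = 0.00746) and oxidative phosphorylation genes (camera adjusted p = 0.0192) were called lower without Myc-labelled replicate 2. Metabolic Myc targets (camera adjusted p = 0.0439), stellate markers (camera adjusted p = 0.0345), cholangiocyte markers (camera adjusted p = 0.00315), cytokines and chemokines (camera adjusted p = 0.00964), monocyte and macrophage markers (camera adjusted p = 0.0366), glycolysis genes (camera adjusted p = 0.00656), oxidative phosphorylation genes (camera adjusted p = 0.0345), fatty acid oxidation genes (camera adjusted p = 0.0287) and immediate early genes (camera adjusted p = 0.0366) were called higher without Myc-labelled replicate 3. Acute phase genes (camera adjusted p = 0.00964) and male-biased genes (camera adjusted p = 0.0104) were called lower without Myc-labelled replicate 3. Interferon response genes (camera adjusted p = 0.00381) were called lower without Myc-labelled replicate 4. Cytosolic ribosomal protein, interferon response, oxidative phosphorylation and fatty acid oxidation genes were thus called in opposite directions depending on the library left out.

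Of 9 library measures, 0 passed after adjustment. Genes above 0 numbered 20572 ± 272 in the controls and 20976 ± 386 in the Myc-labelled libraries (exact permutation p = 0.20, adjusted p = 0.90), and genes of at least 1 TPM 12867 ± 155 in the controls and 13006 ± 489 in the Myc-labelled libraries (exact permutation p = 0.657, adjusted p = 0.914). The 20 most abundant genes held, in percent of TPM, 30.3 ± 1.95 in the controls and 30.5 ± 4.58 in the Myc-labelled libraries (exact permutation p = 0.914, adjusted p = 0.914), and noncoding genes 6.87 ± 1.59 in the controls and 6.63 ± 0.709 in the Myc-labelled libraries (exact permutation p = 0.886, adjusted p = 0.914). Haemoglobin genes held, in percent, 0.0846 ± 0.063 in the controls and 0.116 ± 0.0393 in the Myc-labelled libraries (exact permutation p = 0.371, adjusted p = 0.914). In the same unit, the acute phase genes Saa1 and Saa2 held 1.11 ± 0.795 in the controls and 2.0 ± 2.24 in the Myc-labelled libraries (exact permutation p = 0.657, adjusted p = 0.914). Major urinary protein genes, which can share reads, held 0.275 ± 0.189 in the controls and 0.849 ± 1.24 in the Myc-labelled libraries (exact permutation p = 0.60, adjusted p = 0.914). Aligned bases in Gb were 6.0 ± 0.205 in the controls and 6.05 ± 0.595 in the Myc-labelled libraries (exact permutation p = 0.886, adjusted p = 0.914).

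**Figure D3:**
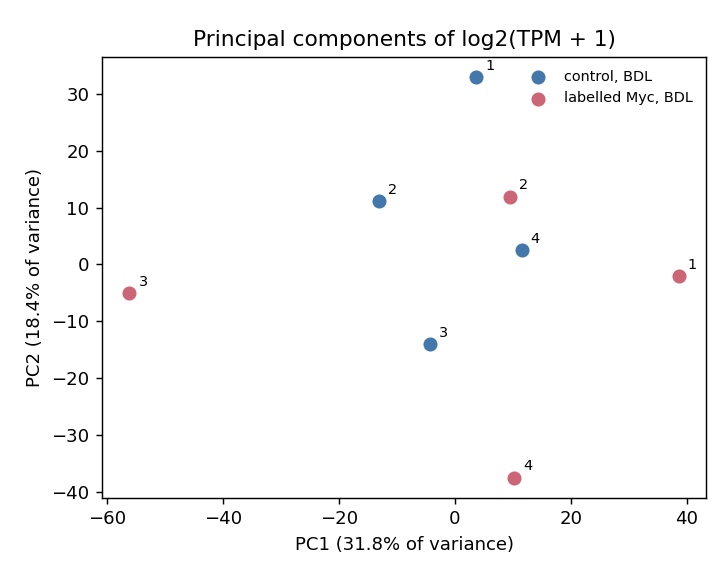
First and second principal components of log2(TPM + 1) over the 13055 tested genes, with replicate numbers beside the points. The axes hold 31.8% and 18.4% of the variance, and Myc-labelled replicates 3 and 1 lie at the opposite ends of the first, with the controls between them.

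Libraries did not fall by group. Pearson correlations across genes, which are not independent replicates, ranged from 0.958 to 0.967 within the controls, from 0.935 to 0.976 within the Myc-labelled libraries and from 0.943 to 0.976 between the groups. Saa1, an acute phase gene, ranged from 316 TPM in control replicate 3 to 23611 TPM in Myc-labelled replicate 3.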

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

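The counts of splits for genes, for lists in both directions together and for Gm43305, and the tests of single libraries, of neighbouring genes and of mixed RNA were chosen only after the result was seen. So was the counting of a split when either of its sides reached the real count, since the direction of other splits is arbitrary. Single libraries stood far from the rest of their group in 8 of 152 groups of 4 values, where chance gives about 7.6. That count does not tell which of the 8 are chance.

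Trdj1 stood at 0.324 TPM in control replicate 3, with the other controls at 0, and at 16.3 TPM in Myc-labelled replicate 1, with the others at 1.79 to 3.01. The tRNA gene mt-Tr stood at 10.8 TPM in control replicate 4, above 5.18 to 5.52 in the others. Iglj1 stood at 2.6 TPM in Myc-labelled replicate 2, above 0 to 0.299 in the others. Robo4 stood at 5.45 TPM in Myc-labelled replicate 1, above 3.5 to 3.77. Hal stood at 99 TPM in Myc-labelled replicate 4, below 144 to 152. Sult3a1, of the female-biased list, was listed at 0 in control replicate 3, the control with Xist at 0.0543 TPM, against 2.11 to 2.33 in the other controls. Ifit2 stood at 8.39 TPM in control replicate 4, above 1.24 to 1.72. The interferon response list as a whole had a centred log2 mean of 1.67 there. In the other controls that mean was -0.618 to -0.319, and in the Myc-labelled libraries -0.804 to 0.378.

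The first pattern is the 15 called gene lists, for which chance could not be excluded: of 35 splits of the 8 libraries, 31 gave at least the 7 higher lists (highest other 14), 25 at least the 8 lower lists (highest other 14) and 18 at least 15 in both directions (highest other 20). For genes all 35 splits reached the 0 found in each direction (highest other 1), but any split reaches 0, so this count decides nothing. At an unadjusted p under 0.05 other splits gave 146 to 1518 genes against 243. Whether a structure of the samples other than the groups lies behind this was not tested. Leaving out 1 library kept at least 9 of the 15 calls (without control replicate 4). A single library stays open for ribosome biogenesis, matrix, TGF-beta, hepatocyte and periportal genes, each of which lost its call without 1 library or more. With log2 Xist as a covariate 10 of the 15 lists stayed called. Other splits gave as many calls with the same test. The counts kept therefore do not decide whether a single library, or unequal numbers of libraries with Xist, was the whole cause. That covariate ended 5 calls, with the mean log2 difference (± SD over members) going from -0.07 ± 0.25 to 0.02 ± 0.25 for pan-endothelial, -0.09 ± 0.73 to -0.02 ± 0.64 for xenobiotic, 0.51 ± 0.23 to 0.48 ± 0.26 for erythroid and platelet, 0.24 ± 0.32 to 0.21 ± 0.29 for stress and -0.67 ± 0.69 to -0.08 ± 0.75 for female-biased genes (to -0.0847), so the unequal numbers remain a candidate explanation for the last and open for the other 4, as does an effect of endothelial Myc, which was not tested. A single library stays open for these 5 lists too, since each lost its call without 1 library or more and the mean before the covariate was, in the order of the libraries, -0.02, -0.12, -0.13, 0.00104, -0.21, -0.00176 and 0.00718 without control replicates 1, 2, 3 and 4 and Myc-labelled replicates 1, 3 and 4 for pan-endothelial; -0.02, 0.00277, -0.22, 0.24 and -0.17 without control replicates 3 and 4 and Myc-labelled replicates 1, 3 and 4 for xenobiotic; 0.80 and 0.25 without control replicates 1 and 4 for erythroid and platelet; 0.36, 0.39 and -0.00268 without Myc-labelled replicates 2, 3 and 4 for stress; and -1.07, -0.39, -1.12, -1.29, -0.14 and -0.17 without control replicates 3 and 4 and Myc-labelled replicates 1, 2, 3 and 4 for female-biased genes.

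The second pattern is the separation of the groups by Gm43305 and Spaca6. Chance could not be excluded, since 19 of 35 splits had a smallest p at or below the real 5.71e-05, with 1.25e-09 in the most extreme other split. A linked chromosome region that differs between the mice of the 2 groups could also give it: of 39 other tested genes within 1 Mb of either gene 1 separated the groups, Trdj1, where up to 2 lie within chance. This cannot be told apart, since a variant of 1 gene need not move its neighbours, and the bound that would have argued against it was narrowed after the result was seen. An effect of endothelial Myc stays open and untested.

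The third pattern is the place of Myc-labelled replicate 2 in the middle, with the highest or lowest value in 8.25% of genes, where the average is 25%. Greater sequencing depth (6.74 Gb) is argued against, since among genes of at least 50 TPM the share was 7.73%, below 14.2% in the next library. A mixture of RNA from the other libraries cannot be told apart: of 6188 protein-coding genes with a mean of at least 10 TPM 0 lay over 2-fold outside the range of the other 7 libraries, against 7 to 91 in each other library, but few such genes restate the pattern itself and decide nothing. A first test, on genes found almost only in 1 other library, had 1 usable gene, Ighv1-81, decided nothing and was then replaced. Cfd, at 43.2 TPM there and listed at 0 in the other 7, goes against a mixture but is 1 gene chosen after its values were seen, and no biological explanation was tested.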

How the results depend on the processing

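The Xist covariate and the run on protein-coding genes were chosen only after the result was seen. In each setting run limma called 0 genes higher and 0 lower, except 1 lower with array weights. Array weights lean most on Myc-labelled replicate 2 (weight 3.32). Higher lists went from 7 to 0 with an estimated correlation and to 0 with fry, and ranged from 4 to 16 when each library was left out in turn. Lower lists went from 8 to 5 without a filter, to 5 with array weights, to 0 with an estimated correlation and to 0 with fry. The Myc log2 difference was 0.23 with array weights and -0.91 to 0.43 over the libraries left out. With array weights the log2 difference turned to -0.28 for Hgf, 0.0271 for Cyp27a1 and -0.0111 for Rsad2, and Ifit2 ranged from -0.57 to 0.12 over the libraries left out. Lists that changed direction and were called on either side had, with array weights, camera adjusted p = 0.000993 for cytosolic ribosomal proteins, 0.00358 for oxidative phosphorylation and 0.927 for female-biased genes. Over the libraries left out the camera adjusted p ranged from 1.07e-08 to 0.969 for cytosolic ribosomal proteins, from 5.55e-06 to 0.273 for interferon response, from 0.0192 to 0.582 for oxidative phosphorylation, from 0.0287 to 0.976 for fatty acid oxidation, from 0.00116 to 0.451 for endoplasmic reticulum stress. The mean log2 difference over members was -0.11 with a mean of at least 5 TPM, -0.11 with median-of-ratios scaling and -0.11 with quantile normalization for pan-endothelial genes, and -0.06 with no filter, -0.06 with FPKM in place of TPM and 0.03 with array weights for xenobiotic genes. It was 0.76 with array weights for erythroid, 0.11 with array weights for stress and -1.14 with a pseudocount of 0.1, -0.40 with a pseudocount of 5 and 0.34 with array weights for female-biased genes. Of 921 list results under other settings 789 kept their direction and side of the threshold or were called in neither, 85 lost a call, 39 gained one and 8 reversed, and among lists called on neither side the direction changed in 88, over 20 lists. Of 1282 results of named genes 1277 kept their direction and side, 1 gained a call and 4 reversed. The difference in genes above 0 was -2.25 among genes with a mean of at least 1 TPM. Over the libraries left out library differences ranged from -70.8 to 327 for genes of at least 1 TPM, from -1.92 to 1.58 for the percent in the 20 most abundant genes, from -0.655 to 0.536 for noncoding percent, from -0.196 to 1.42 for Saa1 and Saa2 percent, from -0.0361 to 0.848 for major urinary protein percent. The cause was not tested. Read counts were not used here, so counting error was not separated from the spread between livers.

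Replicate numbers gave no sign of pairing the samples: deviations of same-numbered libraries correlated at -0.0579 to 0.128, and 1 of 4 Myc-labelled libraries correlated best with its own number. With 4 libraries per group, and litter and batch not given, this cannot exclude a pairing. With the replicate block limma called 0 genes in either direction, and camera 8 higher and 8 lower lists. Pan-endothelial markers were then not called (adjusted p = 0.0511), nor was Selp over its list alone (limma adjusted p = 0.0703), while cytokines and chemokines (adjusted p = 0.0297) were called higher and interferon response genes (adjusted p = 0.0354) lower.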

Other observations

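The test of Myc target lists against the Myc level was chosen only after the result was seen, as were the genes given here.

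The livers differed widely in ways the groups do not give. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, ranged from 5.03 TPM in Myc-labelled replicate 4 to 133 TPM in control replicate 1, and Cyp4a14 from 1.48 TPM in Myc-labelled replicate 3 to 593 TPM in Myc-labelled replicate 1. The B cell chemokine Cxcl13 stood at 384 TPM in control replicate 2 and 86.5 TPM in Myc-labelled replicate 3, against 1.88 to 14.3 TPM elsewhere. Collagen Col1a1 ranged from 3.23 TPM in control replicate 2 to 58.8 TPM in Myc-labelled replicate 1. Sult2a1, a sulfotransferase whose reads can be shared with its paralogs, ranged from 101 to 552 TPM in the libraries with Xist above 30 TPM and from 0 to 0.0926 TPM in the others. No group comparison of these genes passed (limma adjusted p = 1.0 for each).

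Myc varied 21.7-fold over the 8 libraries, more than the groups differed, and 1 hypothesis was that Myc target lists follow its level. Over 39 lists with at least 3 measured members, metabolic Myc targets had the smaller p of the 2 target lists, with Pearson r = 0.793 (exact permutation p = 0.0305, adjusted p = 0.328) and Spearman rho = 0.667 (exact permutation p = 0.0831, adjusted p = 0.648). Without the 2 libraries farthest from the median Myc level r was -0.0619, so the relation rests on those libraries. It was not particular to Myc targets: oxidative phosphorylation genes had r = 0.880 (exact permutation p = 0.013, adjusted p = 0.328) and rho = 0.738 (exact permutation p = 0.0458, adjusted p = 0.596), with r = 0.10 without those 2. Acute phase genes had r = -0.657 (exact permutation p = 0.0757, adjusted p = 0.328) and rho = -0.929 (exact permutation p = 0.00223, adjusted p = 0.0871), with r = -0.973 without those 2. Ribosome biogenesis targets had r = 0.472 (exact permutation p = 0.245, adjusted p = 0.618) and rho = 0.238 (exact permutation p = 0.582, adjusted p = 0.946), with r = -0.156 without those 2. Whether target genes may follow Myc cannot be told apart from chance at 8 libraries (adjusted p = 0.328), and the bound that would have argued against it was narrowed after the result was seen.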
